A study of Rattus norvegicus with 4 samples.

How the data were processed

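INS-1 rat insulinoma cells treated with 10 µM forskolin or with vehicle (DMSO) for 2 h or 16 h were measured on Affymetrix rat gene 1.0 ST arrays, with 1 array in each of the 4 groups. The deposited log2 signals are gene-level RMA values computed by the authors with the Affymetrix Expression Console 1.1.1, per the file headers and the submitters' processing notes. RMA corrects background, quantile-normalizes the arrays and summarizes probes. For each time point the authors also deposited linear intensity values, which equal 2 to the power of the log2 signal, and a linear fold of forskolin over vehicle. A ratio column in other deposited tables divides the forskolin log2 signal by the vehicle log2 signal in all 29214 entries, so it is not a fold change and was not used for any result. Log2 signals differed by at most 5e-05 between deposited tables, and the table with all 4 arrays was used.

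Of 29214 probe sets, 20411 carried 1 gene symbol, 8803 none and 0 several. Symbols were brought up to date with a table of current rat gene names (assembly GRCr8, used for names only): 14570 named probe sets matched by accession, 2834 by symbol and 1127 by synonym, 1880 kept the symbol as deposited, and 4416 symbols were updated. Coordinates are those of the deposited descriptions (RGSC3.4). Of several probe sets for a gene, which 1026 of 18645 genes had, the one with the highest mean over the 4 arrays stood for the gene. A gene was kept if its highest signal over the arrays reached 4.854 log2 units, the median of that quantity, which left 9323 genes. Forskolin arrays count in this filter, so a gene below it on both vehicle arrays was kept only through a higher forskolin signal. Counts over kept members of a list therefore leave out low members that forskolin did not raise.

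Differences are forskolin minus vehicle log2 signals of the same time. With 1 array per group they have no replicate check, so genes were counted by size alone, at least 2-fold higher or lower, and the precision of a single difference could not be estimated from replicates. For scale, the SD of the difference between the vehicle arrays was 0.252 log2 units over genes. Overlaps are given beside the product of the list sizes over the number of genes. The only test used limma 3.58.1 in R 4.3.3 with treatment and time as additive terms on all 4 arrays, eBayes with a trend in the prior, 1 residual degree of freedom per gene and a Benjamini-Hochberg adjusted p below 0.05; a second adjustment ran over the members of each list alone. This step was tested on simulated data for forskolin over both times on 9323 genes. It recovered 9 of 50 genes changed by 0.5 log2 units, 48 of 50 changed by 1, 50 of 50 changed by 2 and 50 of 50 changed by 3, with 15 false calls. Each changed gene had the same change at both times, with normal noise of the spread that the fit had estimated. Genes whose response differs between the times were not simulated, so these rates do not apply to them.

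Before the data were examined, 28 gene lists were fixed from general knowledge of the pathways: immediate-early transcription factors, CREB targets, cAMP pathway components, MAP kinase feedback regulators, beta-cell transcription factors, insulin and secretory granule, glucose sensing and KATP channel, exocytosis, voltage-gated ion channels, G protein-coupled receptors of beta cells, HIF targets, amino acid response and ATF4 targets, endoplasmic reticulum chaperones and unfolded protein response, sterol biosynthesis, cell cycle, circadian clock, inflammatory and NF-kappaB targets, apoptosis regulators, IGF, insulin and mTOR signalling, TGF-beta, BMP and Id genes, ribosomal proteins, oxidative phosphorylation, housekeeping genes, heat shock and stress response, and markers of other islet cells, exocrine and duct cells, fibroblasts and endothelium, and macrophages and leukocytes. For the 24 lists with at least 5 kept members, the median log2 ratio was ranked among 10000 random lists of the same size matched on mean signal in 20 bins (seed 1). The percentile describes these arrays and is no p-value, since genes are not independent replicates. Of 48 medians, 25 lay outside the central 95% of random lists, where 2.40 would by chance if genes were independent.

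Genes named are the 10 highest and the 10 lowest kept genes with a known symbol at each time, the 5 with the largest and the 5 with the smallest difference between times, up to 4 kept members of each list with the largest log2 ratio in either direction, and Ins1, Ins2, Iapp, Mafa, Crem, Nr4a1, Fos, Irs2, Vegfa and Hif1a in any case. Genes named only in the closing section outside this rule were chosen after their values were seen. A few genes that meet the rule are not reported here.

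Alternatives tried were a 1.5-fold threshold, no expression filter, a stricter filter that keeps the upper 33.3% of genes, cyclic loess and a further quantile normalization of the kept genes, the mean of a gene's probe sets, the authors' table of each time point, random lists not matched on signal and, for limma, no trend, a robust prior and no time term. Naming further probe sets by their accession, which applied to 213, and the 1.5-fold threshold with each of the other scalings at 2 h were added after the data were seen. Calculations ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.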

Results

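Gene expression was profiled in INS-1 cells, an insulin-secreting line derived from a rat insulinoma, to describe how beta-cell transcripts respond to short and to prolonged stimulation of the cAMP pathway. Cells received forskolin at 10 µM, a plant diterpene that activates adenylyl cyclase and thereby raises cAMP, or the solvent DMSO alone (vehicle), for 2 h or for 16 h. Each of the 4 groups was measured on 1 Affymetrix rat gene array, so every difference at a single time has no replicate check and carries no p-value. Values are log2 signals. Of 18645 genes on the arrays, 9323 reached the expression filter and were compared. Between any pair of arrays the signals correlated with Pearson coefficients of 0.986 to 0.993 across probe sets. The median of the negative control probe sets lay between 3.22 and 3.39 on the log2 scale, and 26.8% of these controls would have passed the filter, so signals just above it are close to background.

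At 2 h, transcripts known to be induced by cAMP through the transcription factor CREB stood far above vehicle. Rgs2, a brake on G protein signalling, was 17.2-fold higher with forskolin, the orphan nuclear receptor gene Nr4a3 was 14.2-fold higher and Sik1, a kinase gene of the CREB feedback loop, was 9.81-fold higher. Of 25 CREB target genes above the filter, 16 were at least 2-fold higher and 0 were at least 2-fold lower. These 25 are part of 35 measured. Some, such as Nr4a3 with vehicle signals of 3.91 and 3.7, passed the filter only through forskolin, while low members that were not raised dropped out. Their median log2 ratio of 1.93 exceeded that of all 10000 random lists matched on mean expression (percentile 100). Crem, which encodes cAMP-responsive activators and repressors, was 4.65-fold higher, and Nr4a1 was 6.10-fold higher.

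Other lists of early regulators also ranked high among random lists at 2 h, but they overlap with the CREB list and are not separate evidence. Fos, Fosb, Junb, Nr4a1, Nr4a2 and Nr4a3 belong to both the CREB and the immediate-early list. Dusp1 belongs to both the CREB and the MAP kinase list. Of 23 immediate-early transcription factor genes above the filter, from 29 measured, 12 were at least 2-fold higher and 0 lower. Their median log2 ratio was 1.15 (percentile 100). Fos was 6.46-fold, Fosb 7.87-fold and Nr4a2 8.55-fold higher. The vehicle signals of Fos and Fosb, 3.18 and 3.48, were at the level of the negative controls, so their folds are uncertain. Among 17 feedback regulators of the MAP kinase pathway, only 9 had a ratio above 0 and 13 stayed within 2-fold. The 4 that were at least 2-fold higher were led by the phosphatase genes Dusp1 (3.80-fold) and Dusp4 (3.41-fold) and the receptor kinase inhibitor Errfi1 (3.32-fold). The median of this list was 0.25 (percentile 99.97).

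Genes of the amino acid response, many of them targets of the transcription factor ATF4, were also higher at 2 h. Of 23 members, 8 were at least 2-fold higher and the median log2 ratio was 0.60 (percentile 100). Trib3, a pseudokinase gene, was 6.48-fold higher, the amino acid transporter gene Slc1a4 4.37-fold, the cystine transporter gene Slc7a11 3.05-fold and Ddit3, which encodes the stress factor CHOP, 2.90-fold. The 10 genes of the TGF-beta, BMP and Id list above the filter, from 24 measured, had a median of 0.71 (percentile 100). Fst was 17.2-fold, Tgfb2 4.95-fold and Id4 3.46-fold above vehicle. Fst encodes follistatin, which binds activins, and its vehicle signal of 3.48 was near background. Also among the 10 highest genes with a known symbol were the relaxin family receptor gene Rxfp3 (12.2-fold), the actinin gene Actn2 (11.3-fold), the small GTPase gene Diras2 (9.20-fold) and the somatostatin receptor gene Sstr1 (8.73-fold). Tac1, the substance P precursor gene, was 10.1-fold and Ccnd1, the cyclin D1 gene, 9.90-fold higher. The 2 h vehicle signals of Nr4a3 (3.91), Actn2 (3.77), Ccnd1 (3.90), Trib3 (4.04), Slc7a11 (4.19) and Tac1 (4.42) lay below the upper quartile of the negative controls on that array, 4.47, so the size and rank of these folds are uncertain.

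The lowest ratio at 2 h was that of Txnip, whose product restrains glucose uptake and binds thioredoxin. Its log2 signal was 10.05 with vehicle and 6.44 with forskolin, a 12.2-fold lower level. Gata3 was 7.54-fold lower, the tissue factor gene F3 4.38-fold lower, Klhl23 4.06-fold lower and the Txnip paralog Arrdc4 3.74-fold lower. The forskolin signal of Gata3, 3.33, was at the level of the negative controls.

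Transcription factors that maintain beta-cell identity were lower as a group at 2 h. Of 15 members above the filter, 5 were at least 2-fold lower and 1 was at least 2-fold higher, and the median log2 ratio of -0.59 lay below all random lists (percentile 0). Nkx6-1 had a log2 ratio of -1.59, Neurod1 of -1.16 and Rfx6 of -1.01, though the forskolin signal of Nkx6-1 (3.84) was near background. In all, 4 of the 15 had a ratio above 0. The member at least 2-fold higher was Mafa, an activator of insulin transcription, at 2.48-fold above vehicle. The vehicle arrays of the later and earlier time also differed for this list, with a median of -0.23 (percentile 1.78). Cell cycle genes had a median of -0.21 (percentile 0.22, or 4.02 among random lists not matched on expression), although the inhibitor gene Cdkn1b was 2.43-fold higher. The insulin genes had log2 ratios of 0.01 (Ins1) and -0.02 (Ins2), but Ins1, at 13.23 and 13.25, lay above the 95th percentile of the hybridization spike-ins on these arrays (12.84 and 12.92), where the array may compress a difference, and Ins2, at 12.15 and 12.13, lay below it.

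In all, 195 genes were at least 2-fold higher and 131 at least 2-fold lower with forskolin at 2 h. At a 1.5-fold threshold the balance turned, with 436 higher and 815 lower. The lower count also depended on the filter, with 63 genes under a stricter one, and the split on the scaling, with 229 higher and 95 lower after cyclic loess and 223 higher and 88 lower after a further quantile normalization. With these scalings, a combination tried after the data were seen, the 1.5-fold counts were 541 higher and 536 lower and 557 higher and 513 lower, without an excess of lower genes. The median log2 ratio of all compared genes was -0.10 at 2 h, which is why some list medians near 0 ranked above most random lists.

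**Figure D1:**
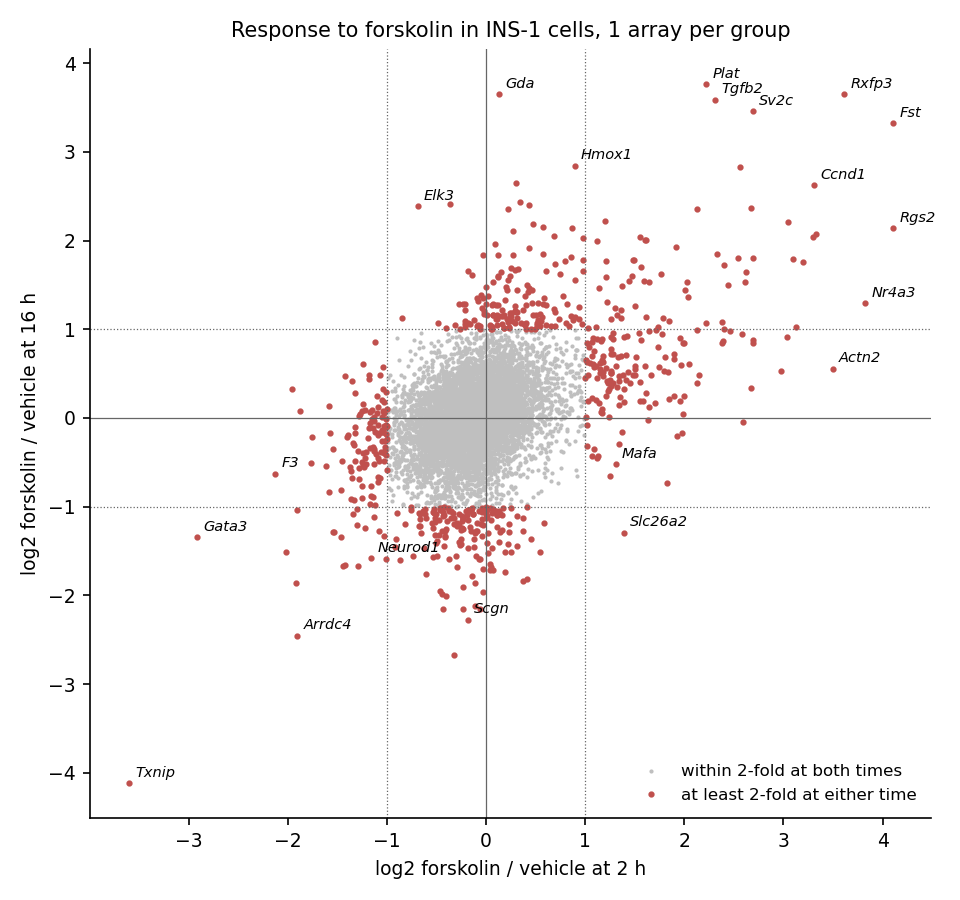
Log2 ratio of forskolin over vehicle at 2 h (horizontal) and at 16 h (vertical) for the 9323 genes compared, with 1 array per group; dotted lines mark 2-fold. Txnip is at -3.61 and -4.12, Rxfp3 at 3.61 and 3.65, while Gda is at 0.13 and 3.65 and Slc26a2 at 1.39 and -1.29.

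After 16 h, the response had a different membership at its extremes. Plat, the tissue plasminogen activator gene, was 13.6-fold above vehicle, Gda, which encodes guanine deaminase, 12.6-fold, Rxfp3 12.6-fold and Tgfb2 12.1-fold. The synaptic vesicle gene Sv2c was 11.0-fold, Fst 9.99-fold, the haem oxygenase gene Hmox1 7.20-fold and Depdc7 7.10-fold higher. At 2 h Hmox1 was 1.86-fold above vehicle and Gda had a log2 ratio of 0.13, or -0.11 after a further quantile normalization. The vehicle signals of Gda (2.97 and 3.36), Depdc7 (3.31 and 3.43), Fst (3.48 and 3.63) and Hmox1 (3.84 and 3.94) were near background, so the size of their folds and their rank are uncertain. Epha5, an ephrin receptor gene, was 6.30-fold higher at 16 h and 1.23-fold at 2 h, from vehicle signals near background.

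Genes regulated by hypoxia-inducible factor (HIF) were higher as a group at 16 h. Of 32 members above the filter, 29 had a log2 ratio above 0, 7 were at least 2-fold higher and 0 were at least 2-fold lower. The median of 0.44 exceeded all random lists (percentile 100), against 0.05 at 2 h (percentile 98.54). The mitophagy receptor gene Bnip3 was 2.51-fold higher, the glucose transporter gene Slc2a1 2.46-fold, the collagen prolyl hydroxylase gene P4ha1 2.44-fold and the phosphofructokinase gene Pfkp 2.05-fold. Hif1a itself was 1.36-fold and Vegfa 1.19-fold above vehicle, and Vegfa had been 1.81-fold above at 2 h. Between the vehicle arrays the median of the HIF list differed by -0.06.

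Endoplasmic reticulum chaperones and sensors of the unfolded protein response moved alike. Of 27 members, 26 had a ratio above 0 at 16 h and the median was 0.63 (percentile 100), compared with 0.01 at 2 h (percentile 86.54). Sdf2l1 was 3.15-fold, the stress sensor gene Ern1 2.29-fold, the co-chaperone gene Dnajc3 2.18-fold and Creld2 2.07-fold higher. Ero1b, an oxidase that supports proinsulin folding, was the single member at least 2-fold lower, by 2.03-fold. Among 17 heat shock and stress genes the metal-binding gene Mt1 was 2.11-fold and the quinone reductase gene Nqo1 2.24-fold higher. The median of that list was 0.19 (percentile 97.14, or 98.70 without the filter and 98.24 after a further quantile normalization), at the edge of the central 95% of random lists, and at 2 h it was 0.11 (percentile 98.94).

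Cell cycle genes were lower at 16 h, with 5 of 34 members above 0 and a median log2 ratio of -0.37 (percentile 0). The mitotic kinase gene Aurkb was 2.13-fold lower on its brighter probe set and had a log2 ratio of -0.31 when its probe sets were averaged. Ccnd1 and the inhibitor gene Cdkn1a, with log2 ratios of 2.63 and 1.77, were higher against that trend. Beta-cell transcription factors stayed below vehicle, with a median of -0.52 (percentile 0), and 2 of 15 were at least 2-fold lower, namely Rfx6 and Neurod1, with log2 ratios of -1.59 and -1.58. Mafa, higher at 2 h, had a log2 ratio of -0.52. Among 14 G protein-coupled receptor genes of beta cells, 5 were at least 2-fold lower and 1 higher (median -0.27, percentile 0.57). The free fatty acid receptor genes Ffar3 and Ffar1 were 3.18-fold and 3.04-fold and the purinergic receptor gene P2ry1 2.43-fold lower. With probe sets named by accession added, which was tried after the data were seen, the median of this receptor list was -0.08 (percentile 14.71).

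**Figure D2:**
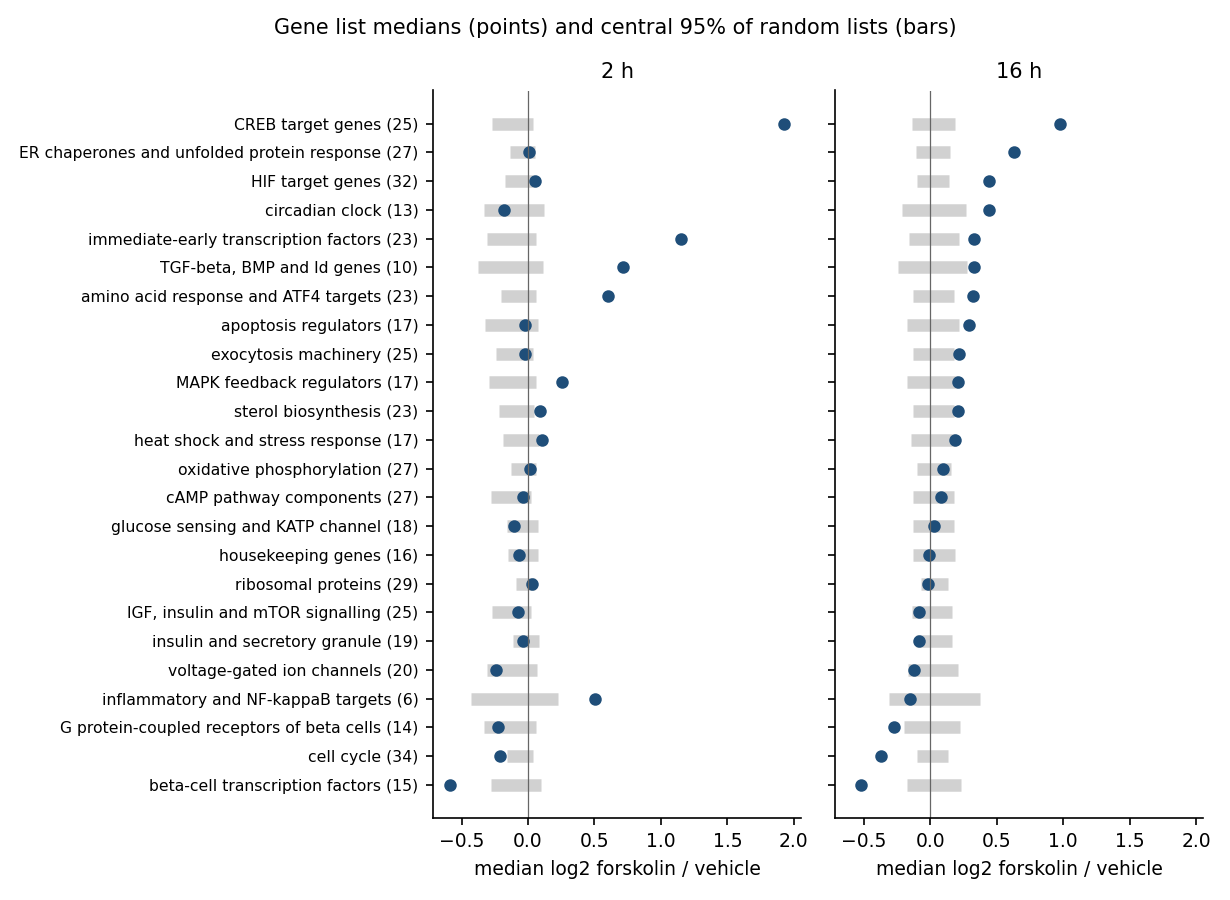
Median log2 ratio of forskolin over vehicle for 24 gene lists (points; number of genes above the filter in brackets) at 2 h and 16 h, with the central 95% of the medians of 10000 random lists of the same size and mean expression (bars). CREB targets are highest at both times, with medians of 1.93 and 0.98, and beta-cell transcription factors lowest, with -0.59 and -0.52.

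At 16 h the log2 ratios of insulin and amylin transcripts, with the same limit for Ins1, were -0.09 for Ins1, -0.24 for Ins2 and 0.36 for Iapp. The insulin and secretory granule list had 1 of 19 members at least 2-fold higher, the granin-like gene Vgf at 2.75-fold, and 1 lower, Ero1b; its median was -0.09 (percentile 4.27), or 0.05 without the filter (percentile 69.31) and 0 after a further quantile normalization (percentile 59.46), so its sign depends on the processing. The peptide-amidating enzyme gene Pam was 1.90-fold and the granin gene Scg3 1.80-fold higher. Of 18 glucose sensing and KATP channel genes, 3 were at least 2-fold higher at 16 h, Slc2a1, Pfkp and the lactate transporter gene Slc16a1 (2.34-fold), and 1 was lower, the pyruvate kinase gene Pklr (2.41-fold); the median was 0.03 (percentile 55.34).

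Exocytosis genes had a median of 0.21 at 16 h (percentile 99.16, or 96.45 under the stricter filter) and of -0.02 at 2 h (percentile 85.38), or 0.05 without the filter (percentile 97.66). The calcium sensor gene Syt4 was 2.40-fold, Doc2b 2.44-fold (from a vehicle signal of 3.62, near background) and the SNARE gene Snap25 2.04-fold higher, and Rab3b was 2.73-fold lower. This list was also lower in the 16 h than in the 2 h vehicle array, by a median of -0.24 (percentile 0.21). Voltage-gated ion channel genes had medians of -0.24 at 2 h (percentile 10.27) and -0.12 at 16 h (percentile 6.61), or -0.36 and -0.30 under the stricter filter (percentiles 2.01 and 0.87), with Kcnma1 2.16-fold higher and Cacna1a 2.43-fold lower at 16 h. Among the lowest ratios of all genes at 16 h were those of Txnip (17.3-fold lower), Arrdc4 (5.48-fold), the calcium-binding protein gene Scgn (4.83-fold), Plppr1 (4.46-fold), the selenium carrier gene Selenop (4.44-fold) and the arginase gene Arg1 (4.35-fold). The forskolin signal of Selenop, 3.48, was at the level of the negative controls, so its fold and rank are uncertain. Scgn, with a vehicle signal of 10.96, and Arg1, with 8.46, were well above background and had log2 ratios of -0.19 and -0.12 at 2 h.

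Altogether 217 genes were at least 2-fold higher and 188 at least 2-fold lower at 16 h, the latter 121 under the stricter filter. The CREB target list kept a median of 0.98 (percentile 100), with 12 of 25 members at least 2-fold higher. The immediate-early list had a median of 0.33 (percentile 99.87, or 96.50 without the expression filter). Of its 23 members, 15 lay above 0, 4 were at least 2-fold higher and 2 at least 2-fold lower. The amino acid response list had a median of 0.32 (percentile 100), with 21 of 23 members above 0 and 3 at least 2-fold higher.

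Comparison of the time points addressed how far prolonged stimulation resembles the short one. Forskolin responses at 2 h and 16 h shared part of their genes: 61 genes were at least 2-fold higher at both times, where independent lists of those sizes would share 4.54, and 21 were lower at both, where 2.64 would be shared. Each time had its own vehicle array, so no control was shared. The log2 ratios of the 9323 genes correlated with Pearson r = 0.43 and Spearman rho = 0.35 across genes, which are not independent replicates. Of the 195 genes at least 2-fold higher at 2 h, 179 had a ratio above 0 at 16 h. Their median log2 ratio was 1.48 at 2 h and 0.70 at 16 h, and the 217 genes higher at 16 h had 1.29 there and 0.45 at 2 h. Choosing genes for a high ratio on single arrays lowers the value at the other time by itself, so these medians do not show that the response weakens. For CREB targets the median of the 16 h minus 2 h differences was -0.91 (percentile 0), for immediate-early factors -0.76 (percentile 0). HIF targets and endoplasmic reticulum genes went the other way, with median differences of 0.42 and 0.52 (percentile 100 each).

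Single genes at the ends of this range differed by several log2 units. Gda, Elk3, Fgb, Epha5 and Slc2a9 had the largest 16 h minus 2 h differences, 3.53, 3.08, 2.77, 2.35 and 2.14. Actn2, Slc26a2, Cd83, Nr4a3 and Fosb had the smallest, -2.94, -2.68, -2.64, -2.53 and -2.45. Cd83, a surface protein gene of activated lymphocytes, was 6.02-fold higher at 2 h and had a log2 ratio of -0.05 at 16 h. Only Slc26a2, a sulphate transporter gene, was at least 2-fold higher at 2 h (2.61-fold) and at least 2-fold lower at 16 h (2.45-fold), and 0 genes showed the opposite order. The difference between the times was not tested.

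**Figure D3:**
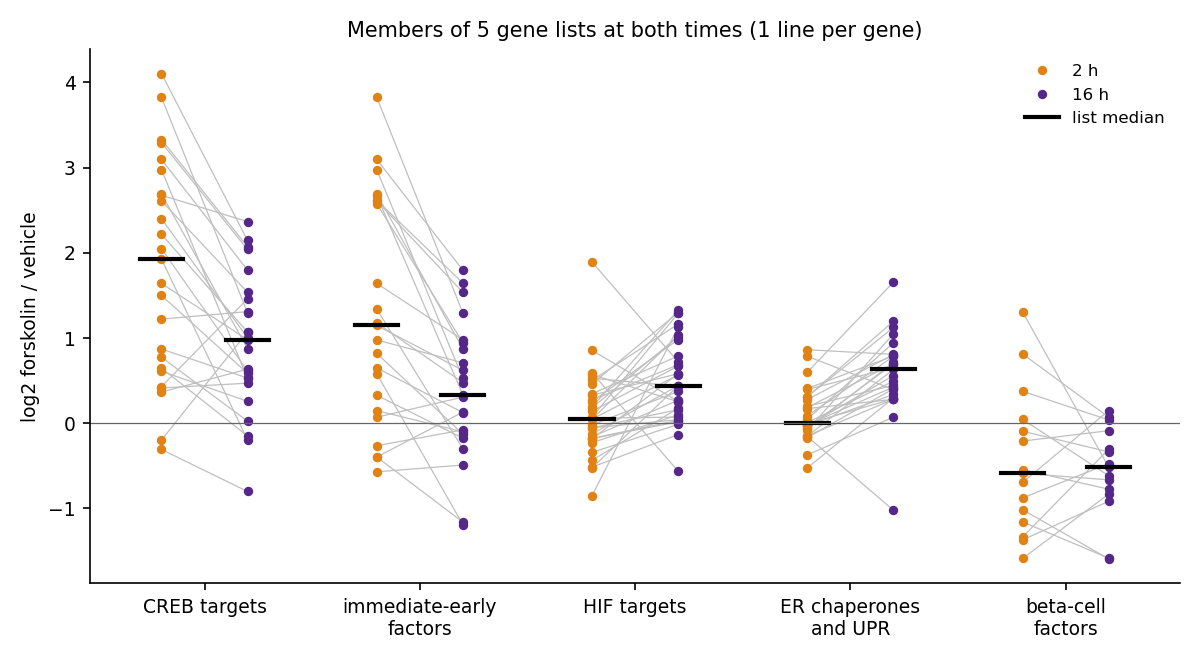
Log2 ratio of forskolin over vehicle of each gene above the filter in 5 lists, at 2 h (orange) and 16 h (purple), with a line joining the values of a gene and a black bar at the list median. CREB target medians are 1.93 and 0.98, immediate-early 1.15 and 0.33, HIF target 0.05 and 0.44, endoplasmic reticulum 0.01 and 0.63, and beta-cell factor -0.59 and -0.52.

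Both times together allowed the one test in this design, limma with treatment and time as additive terms on all 4 arrays. It asks whether the mean of both log2 ratios differs from 0. The spread comes from the disagreement between the times, where a gene's own part has 1 residual degree of freedom. The prior, estimated over all genes by their signal, has 8.03, so most of the spread used for a gene is shared. Nr4a3, with ratios of 3.82 and 1.29, could therefore pass. The p-values rest only on such disagreement, more over all genes than in the gene itself, since nothing says that cultures were replicated. With limma, 91 genes rose and 23 fell at a Benjamini-Hochberg adjusted p below 0.05, and 1315 of 9323 had an unadjusted p below 0.05. Txnip fell by 3.86 ± 0.19 on the log2 scale (SE of the limma fit, adjusted p = 7.1e-05). Rxfp3 rose by 3.63 ± 0.20 (limma adjusted p = 9.2e-05), Fst by 3.71 ± 0.27 and Sv2c by 3.07 ± 0.23 (limma adjusted p = 0.00062 each), and Ccnd1 by 2.97 ± 0.26 (limma adjusted p = 0.0015). Arrdc4 fell by 2.18 ± 0.21 (limma adjusted p = 0.0024), and Tmem215, Klhl23, Gata3 and Adora2b fell as well. A gene that responds at 1 time counts here as spread, so Actn2, with limma adjusted p = 0.14, and Gda, with 0.24, did not pass.

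By list, limma found that 11 of 25 CREB targets rose and 0 fell over all genes tested, and 18 rose and 1 fell when adjusted over the list alone. Among immediate-early factors 5 rose, and 12 rose and 1 fell adjusted over the list alone. The 5 include Nr4a1, Nr4a2, Nr4a3 and Junb, which count among the CREB targets as well. Of the amino acid response list 3 rose (12 adjusted over the list alone), among them Trib3, Slc7a11 and Ddit3, and of the MAP kinase feedback list 3 rose (3 adjusted over the list alone), Dusp4, Spry1 and Errfi1. Neurod1 and Rfx6 fell, 2 of 15 beta-cell factors (8 adjusted over the list alone), as did the receptors Ffar3, Ffar1 and P2ry1, 3 of 14 (6 adjusted over the list alone, where 2 others rose). In the HIF and endoplasmic reticulum lists 0 genes passed over all genes tested, and 4 and 7 rose adjusted over the list alone. Cell cycle genes gave 2 that rose and 0 that fell by limma (3 and 5 adjusted over the list alone), TGF-beta, BMP and Id genes 2 that rose (4 adjusted over the list alone) and exocytosis genes 1 that rose, Syt4 (1 adjusted over the list alone). In the granule, glucose sensing, heat shock and ion channel lists limma passed 0 genes over all genes tested. Adjusted over the list alone, 2 rose and 2 fell, 3 rose and 3 fell, 3 rose and 0 fell, and 0 passed. Igf1r, the insulin-like growth factor receptor gene, rose by 1.19 ± 0.21 (limma adjusted p = 0.033). The limma counts depended strongly on the setting: 1 gene rose and 1 fell after cyclic loess, 20 and 4 after a further quantile normalization, 19 and 3 without the filter, and 138 and 68 under the stricter filter.

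**Figure D4:**
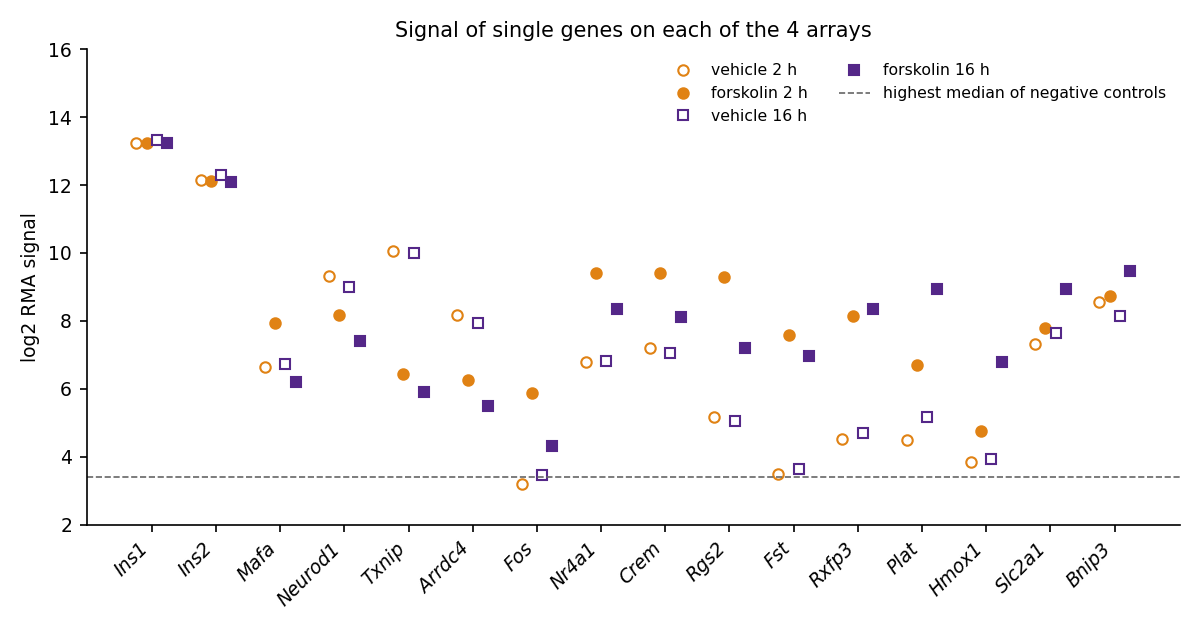
Log2 RMA signal of 16 genes on each of the 4 arrays (orange circles 2 h, purple squares 16 h; open vehicle, filled forskolin), with a dashed line at the highest median of the negative controls, 3.39. Ins1 lies between 13.23 and 13.32 on all arrays, whereas Txnip is at 10.05 and 10.01 with vehicle and at 6.44 and 5.90 with forskolin.

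Remaining lists showed smaller or mixed differences. Of 27 cAMP pathway components, 4 were at least 2-fold higher at 2 h and 5 higher and 1 lower at 16 h, where Rgs16 was 3.57-fold lower, and medians were -0.04 (percentile 88.02) and 0.08 (percentile 77.18). The 2 h median of these components was 0.14 without the filter (percentile 99.90), 0.37 under the stricter filter (percentile 100) and 0.12 with the mean of a gene's probe sets (percentile 99.88), so its direction depends on the processing. In this list limma found that 3 rose (4 rose and 1 fell adjusted over the list alone). The 3 are Crem, Sik1 and Rgs2, which count among the CREB targets as well. Sterol synthesis genes had medians of 0.09 and 0.21 (percentiles 99.36 and 99.02), but 0.03 at 2 h with the mean of a gene's probe sets (percentile 96.19) and 0.17 at 16 h with probe sets named by accession added (percentile 96.92), with limma finding that 1 rose (4 adjusted over the list alone); Insig1 rose by 0.82 ± 0.14 (limma adjusted p = 0.033). Of 13 clock genes the median was -0.18 at 2 h (percentile 25.29), or 0.27 under the stricter filter (percentile 98.70), and 0.44 at 16 h (percentile 99.89), and the repressor genes Cry2 and Nfil3 were 5.21-fold and 5.28-fold higher at 2 h; both rose by limma, with adjusted p = 0.018 and 0.035, and adjusted over the list alone 3 rose and 2 fell. Only 6 inflammatory genes passed the filter, with a median of 0.50 at 2 h (percentile 99.89, or 96.36 without the filter) and -0.15 at 16 h (percentile 14.07, or 0.56 without the filter), and limma passed 0 of them by either adjustment. Apoptosis regulators had medians of -0.02 (percentile 84.14) and 0.29 (percentile 99.58, or 81.57 without the filter, 85.54 under the stricter one and 94.02 with the mean of a gene's probe sets), with the proapoptotic gene Bcl2l11 2.67-fold higher and Bcl2l1 having a log2 ratio of -1.09 at 2 h; limma passed 0 of them over all genes tested, and 2 rose and 2 fell adjusted over the list alone. Genes of IGF, insulin and mTOR signalling had medians of -0.07 and -0.08 (percentiles 74.86 and 10.1), and by limma 1 rose and 1 fell (4 and 1 adjusted over the list alone); Irs2 was 1.83-fold and 1.44-fold higher. After cyclic loess the 2 h medians of the cAMP component, apoptosis, IGF and exocytosis lists were 0.07, 0.06, 0.04 and 0.02, so their sign depends on the scaling. MAP kinase feedback genes had a median of 0.21 at 16 h (percentile 97.68, or 48.34 under the stricter filter and 97.31 among random lists not matched on expression), and the TGF-beta list one of 0.33 (percentile 98.81).

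Lists without an expected response lay near 0. Ribosomal protein genes had medians of 0.03 and -0.02 (percentiles 90.7 and 18.94), oxidative phosphorylation genes 0.02 and 0.10 (percentiles 87.43 and 87.85) and housekeeping genes -0.07 and -0.01 (percentiles 27.81 and 30.86), and 0 of their members differed 2-fold at either time or passed limma by either adjustment. Of 13 macrophage and leukocyte markers 0 passed the filter, and of 16 fibroblast and endothelial markers on the arrays 3 did. Of 14 markers of other islet cells 4 passed, with the glucagon gene Gcg at a log2 signal of 11.76 in the 2 h vehicle array and at log2 ratios of 0.24 and 0.61. Of 17 exocrine and duct markers 3 passed, among them the keratin gene Krt8 at log2 ratios of 0.06 and 0.34 and Ctrb1, 2.07-fold higher at 16 h.

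The vehicle arrays differed from each other far less than from the forskolin arrays. Between 16 h and 2 h of vehicle, 11 genes differed at least 2-fold, 8 higher and 3 lower at 16 h, against 326 and 405 with forskolin at 2 h and 16 h. The count was 19 without the filter and 4 under the stricter one. The SD of the log2 differences over genes was 0.25 for the vehicle arrays, 0.45 for forskolin at 2 h and 0.46 at 16 h. Time in culture and array differences cannot be separated in this pair. Between the vehicle arrays, amino acid response genes had a median of 0.17 (percentile 99.99), oxidative phosphorylation genes 0.13 (percentile 100) and ion channel genes -0.32 (percentile 0.05). The 6 inflammatory genes had a median of 0.26 (percentile 99.77) in this pair, beside 0.50 with forskolin at 2 h.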

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

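The naming of probe sets by accession and the count without copies were chosen only after the values were seen. With forskolin, 3 of the genes named differed at least 1.5-fold at each time but in opposite directions at 2 h and 16 h: the ETS factor gene Elk3 at -0.69 and 2.39 (16 h minus 2 h difference 3.08), the sulphate transporter gene Slc26a2 at 1.39 and -1.29 (difference -2.68) and the clock repressor gene Nr1d1 at -1.25 and 0.61 (difference 1.86). The differences between times were not tested, since each group has 1 array. Nr1d1 had a forskolin signal of 4.48 at 2 h, close to background. The vehicle signals of Elk3 were 5.82 at 2 h and 5.11 at 16 h, a difference of -0.71. Its 2 h ratio is no larger than that, so its lower level at 2 h is uncertain.

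Probe sets without a gene symbol, which no count of genes includes, also differed with forskolin. Of 1691 at or above the expression filter, 49 differed at least 2-fold at 2 h (31 higher, 18 lower) and 83 at 16 h (26 higher, 57 lower), against 24 between the vehicle arrays (22 higher, 2 lower). Some are copies with identical signals: with each set of signals counted once, 49 differed at 2 h, 77 at 16 h (26 higher, 51 lower) and 19 between the vehicle arrays. Of the 51 lower at 16 h, 35 had a higher vehicle signal at 16 h than at 2 h, and 21 were also at least 2-fold below the vehicle signal of 2 h. Accessions assign a few of these to genes. The probe set of Kdr, a vascular endothelial growth factor receptor gene, had log2 ratios of 3.73 at 2 h and 2.12 at 16 h, from vehicle signals near background (4.13 and 3.82), and a pair assigned to Fosl2, an AP-1 factor gene, had 3.34 and 3.18 at 2 h and 2.23 and 2.02 at 16 h. A probe set described as a pseudogene on chromosome 1 (123522372 to 123522552, RGSC3.4) had ratios of -2.59 and -2.99. Which transcript it measures was not tested.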

How the results depend on the processing

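Among the alternatives below, the naming of further probe sets by accession and the 1.5-fold threshold with another scaling were chosen after the data were seen. The limma fit compares forskolin with vehicle within each time; no further pairing was possible because each group has 1 array and replicate numbers were only given in accession order, and leaving out an array would leave limma no residual degrees of freedom. Signals within the range of the negative controls limit every fold that rests on them. At a 1.5-fold threshold, 436 genes were higher and 815 lower at 2 h, 716 higher and 632 lower at 16 h, 189 higher and 141 lower at both times, and 290 differed between the vehicle arrays. A lower threshold admits more genes by construction, but that does not account for the excess of lower genes at 2 h, which ended with 541 higher and 536 lower after cyclic loess and 557 higher and 513 lower after a further quantile normalization. The stricter filter gave 63 lower at 2 h, 121 lower at 16 h and 4 between the vehicle arrays, and limma 138 that rose and 68 that fell. Without the filter 19 differed between the vehicle arrays, and limma gave 19 and 3. Limma further gave 1 and 1 after cyclic loess, 20 and 4 after a further quantile normalization, 32 and 7 with no trend in the prior and 11 and 1 with no time covariate. The prior degrees of freedom, which set the weight of the spread shared over genes, were 8.03 in the main setting and 12.8 under the stricter filter. They were 5.75 without the filter, 5.15 with no trend and 4.60 with no time covariate. After a further quantile normalization they were 4.59, and after cyclic loess 4.09. Of these settings, those with fewer calls than the main one had lower values, though not in strict order. The cause of these shifts in limma counts was not tested further. Of 95 counts and correlations under alternatives, 68 lay within 1.5 times the main value, which still admits 88 genes lower at 2 h in place of 131, and 27 did not. Of 382 list medians under alternatives, 359 kept their place relative to the central 95% of random lists, 10 moved out of it and 13 into it. For the named genes 1374 of 1378 log2 ratios stayed within 0.252 of the main value, the SD between the vehicle arrays, and 4 moved: Epha5 at 2 h to 0.05 after quantile normalization, Fdps to 0.20 at 2 h and 0.14 at 16 h with probe sets named by accession added, and Aurkb at 16 h to -0.31 with the mean of its probe sets. None of these 4 changed direction, but 18 of the 1378 reached 0 or turned sign, all with main values at most 0.13 from 0, such as Gda at 2 h (-0.11 after quantile normalization). Likewise 19 of the 382 list medians, of 8 lists at 1 time each the farthest of which has a main median of -0.18, reached 0 or turned sign. The correlation across genes ranged from 0.32 without the filter to 0.48 under the stricter one.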

Other observations

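Tests chosen only after the result was seen are those on histone genes, on the ratio column, on the vehicle arrays, on MondoA and ChREBP targets, and on snoRNA copies, other unnamed probe sets, other small RNAs and the size of the host gene response, while cyclic loess was chosen beforehand and its use against a trend decided after. Histone genes, 22 by symbol above the filter, had a median log2 ratio of 0.07 at 2 h (percentile 98.0) and of -1.03 at 16 h (percentile 0), where 22 of 22 lay below 0 and 13 were at least 2-fold lower. The 16 h median was -1.03 after cyclic loess, -1.09 after a further quantile normalization and -0.999 with the mean of a gene's probe sets, with 22 below 0 in each. Copies of a histone gene share near-identical sequence, so these are not 22 independent values, and between the vehicle arrays the median was 0.19 (percentile 100).

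The deposited quotient of log2 signals ranks genes differently from the fold. Of the 100 highest genes by fold, 79 at 2 h and 73 at 16 h were among the 100 highest by the quotient. A quotient of at least 2 was reached by 2 genes at 2 h and 1 at 16 h, against 195 and 217 by fold. These thresholds are not alike, since a quotient of 2 asks for a log2 signal 2 times that of vehicle. For the same fold, the quotient is smaller at a higher signal, which changes the ranking.

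HIF target genes were higher with forskolin at 16 h. Random lists matched on signal already allow for a trend of the ratio with signal, so the list's place after cyclic loess (percentile 100) adds little. The rise was not limited to glycolysis genes: the 20 members outside glycolysis had a median of 0.50 (percentile 100) beside 0.40 for 12 glycolysis genes. These members are part of the same list, of which 29 of 32 lay above 0, so this describes the list and is no separate test. A further list of HIF targets, written before its values were seen, had a median of 0.28 for 20 genes (percentile 99.86), so more HIF activity is a candidate explanation. A difference between the 16 h cultures unrelated to forskolin cannot be told apart, since the only like-treated pair, the vehicle arrays (percentile 48.66), differs in time.

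Txnip and its paralog Arrdc4 were among the lowest genes at both times. A trend of the ratio with signal is argued against, since their ratio nearest 0 after cyclic loess was -1.80. Glucose-sensing factors MondoA and ChREBP activate both genes, and 15 other targets had a median of -0.05 at 2 h (percentile 62.83), which decides nothing for members that go both ways. At 16 h the median was -0.19 (percentile 1.43), with Pklr (-1.27), Klf10 (-1.16) and Rgs16 (-1.84) lower and Arrdc3 (1.44) higher, and 12 of 15 lay below 0 under each scaling. However, Pklr, Klf10, Rgs16, Acaca and Acly also belong to lists fixed and read earlier. Unlike in the further HIF list, such genes were not left out, so this percentile is not a separate test. A probe set assigned by accession to Mlxipl, the ChREBP gene, had log2 ratios of -0.41 at 2 h and -1.33 at 16 h. Its vehicle signals were 8.19 and 7.91. It was picked after its values were seen, and a transcript level does not measure activity. Less activity of these factors at 16 h is therefore only a candidate explanation. The vehicle arrays differed by a median of -0.19 as well (percentile 4.91), and a culture difference was not excluded.

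Probe sets of snoRNAs were higher with forskolin at 2 h, with a median of 0.50 over 131 distinct signals (112 above 0), and not at 16 h, with -0.12 (49 above 0); a cluster of 14 on chromosome 1 (110868196 to 111472335, RGSC3.4) had -0.11 at 2 h, against 0.51 for the 117 elsewhere. Copies counted several times are argued against by that median of distinct signals, and a shift of all unnamed probe sets by its percentile of 100 among others of like signal. For 28 genes listed as snoRNA hosts, a rise as large as that of the snoRNAs is argued against. Of these genes, 90% lay at or below 0.21 and 1 reached the snoRNA median. A smaller rise stays open (median 0.03, percentile 91.67, list written beforehand). The listed genes were not matched by position to the snoRNA probe sets. A rise of the actual hosts of the snoRNAs that rose therefore stays open too. More small RNA of every kind on that array also stays open: the median was 0.12 for miRNA and snRNA probe sets together, 0.17 for snRNA, 0.54 for rRNA, and among miRNA probe sets -0.0015 (14 of 29 above 0, against such a rise) and, for stem-loops, 0.15 (22 of 30 above 0), and rRNA differed by 0.67 between the vehicle arrays as well. With 1 array, these open explanations cannot be told apart from a response to forskolin.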
